A study of Arabidopsis thaliana with 11 samples.

How the data were processed

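RNA from Arabidopsis thaliana Columbia-0 leaves (3 samples), stems (4 samples) and flowers (4 samples) was hybridised to 11 Affymetrix ATH1 GeneChips. Per the labels, leaf RNA was prepared with Trizol alone, and stem and flower RNA with Trizol followed by a silica column. The authors made the deposited signal intensity with Microarray Suite 5.0 at a target of 500, and the labels state a further scaling of each array to a GapC signal of 8500. The deposited intensity was tested for both steps. Each column had a 2% trimmed mean of 500, so the GapC factor had not been applied to the values. For 7 of the 11 arrays the GapC signal times the stated factor came within 1 unit of 8500. For stem replicates 2 and 3 and flower replicates 2 and 3 the factor stated for 1 array of each pair matched the other array.

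The deposited values were rescaled to a 2% trimmed mean of 500, quantile normalised over the 11 arrays and transformed as log2(value + 32). The 64 control probe sets were left out. Of the 22810 probe sets in the table, 17526 had a normalised intensity of at least 100 in at least 3 arrays and were tested. Detection calls were not used here. Folds are differences on this scale and are therefore smaller than ratios of raw intensity for weak signals. The number of arrays limits the precision of every value.

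Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). A probe set was called when its Benjamini-Hochberg adjusted p was under 0.05 and its absolute log2 fold change was at least 1. All p-values were two-sided. The 3 tissue contrasts came from 1 fit to all 11 arrays. The contrast of greenhouse with growth chamber used tissue as a covariate in 10 arrays. Stem replicate 4 was left out of it because its title code gives the greenhouse and its protocol text a growth chamber. A further fit of tissue, site and their interaction to those 10 arrays tested whether the site effect differed between tissues. That fit had cells with 1 array each (growth chamber leaf and greenhouse stem), which were assumed to vary like the others. A probe set was called enriched in a tissue when it was called higher there than in both other tissues, and depleted when called lower than in both. The labels do not say whether replicates came from separate plants or pools, so p-values measure the spread between these samples. The labels gave replicate numbers but no pairing of them across tissues.

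Gene names came from the platform's probe table. It gave 1 gene for 13513 probe sets, several for 503 and none for 8730. Of the tested probe sets, 9810 had 1 gene and 1331 of these had a symbol other than the bare locus tag. A gene table of assembly TAIR10.1 was used for names only, and matched 13436 probe sets. GapC was taken from the probe set the labels name. That probe set was not paired with a single gene. GapC and PDF1.2b were each read by a probe set whose suffix marks probes that can hybridise to related transcripts.

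Before the data were examined, 22 gene lists with 349 genes were fixed by locus. Only 47 of these genes had a probe set with a name, and 43 were tested. The lists with at least 3 tested genes were Calvin cycle, photorespiration, tapetum and pollen wall, pollen, mitotic cell cycle, flavonoid synthesis, heat shock, and cold and abscisic acid. Lists with 1 or 2 tested genes are given as single genes: photosystems and light harvesting, flowering time, secondary cell wall, monolignol synthesis, cuticular wax, cell wall loosening, glucosinolate synthesis and breakdown, pathogen defence, circadian clock, and light stress. No member was tested for floral organ identity, seed storage, meristem and vascular patterning, or jasmonate. After the coverage of the probe table had been seen, 40 families of at least 5 tested genes were added, by the leading letters of the symbol or as plastid-encoded groups. The 48 lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, with 1 probe set per gene and adjustment over the 48 lists of a contrast. Only the camera results are given here.

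The rule for named genes was fixed before the data were examined. Per contrast it took called genes with a symbol whose groups did not overlap, the 6 largest positive and the 6 largest negative. It added 2 called members in the direction of each list that passed, up to 2 called against it, called secondary cell wall genes in the stem contrasts, and GapC. Other genes are members of fixed lists, or were chosen after their values were seen where so stated.

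The alternatives were other scalings (GapC, trimmed mean only, median centring), a pseudocount of 1 or 100, no filter or a signal minimum of 200, no trend, no minimum fold, site as a covariate, a replicate block, only the 2 tissues compared, other site assignments, flower arrays only, and leaving out each array. The pipeline was tested on simulated data with planted changes. It called 91.0% of planted 4-fold changes in flower versus leaf, 83.6% in stem versus leaf, 91.0% in flower versus stem and 97.0% between sites. For planted 2-fold changes the calls were 19.4%, 28.4%, 26.9% and 29.9%. A 2-fold change lies exactly at the fold threshold, which limited these shares. The adjusted p threshold also applied, and the effects of the 2 thresholds were not separated. For the difference of the site effect between flower and stem, 5.97% of planted 4-fold and 39.4% of 8-fold changes were called. Only 66 or 67 of 17526 probe sets were changed per fold, with independent noise. These shares are therefore not the power of the real contrasts. In the tissue contrasts many more probe sets differed, and for the site contrasts the independent noise remains a limit. Plots were drawn with Python 3.11.15 and matplotlib 3.10.9.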

Results

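Transcript levels of Arabidopsis Columbia-0 were measured on ATH1 arrays in expanding leaves (3 arrays), the upper 2 inches of the stem (4 arrays) and flowers (4 arrays). Leaves were harvested on day 15 and stems and flowers on day 29 after germination. Plants grew at 25 °C by day and 20 °C by night, in a growth chamber or a greenhouse. Of the 10 arrays with a single stated site, 5 came from each. The median signal per array was 192 to 251. In leaf, 65.3% ± 0.413 (SD, n = 3) of probe sets had a signal of at least 100, against 66.0% ± 0.515 (SD, n = 4) in stem and 70.4% ± 1.04 (SD, n = 4) in flower.

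Arrays of 1 tissue resembled each other most. Across probe sets, which are not independent replicates, Pearson's r was at least 0.904 within a tissue and at most 0.824 between tissues. The first principal component held 40.9% of the variance and the second 31.1%. The lowest mean r with its own tissue was 0.908, in stem replicate 3. This array also had the highest 3'/5' signal ratios of the control transcripts, 12.2 for actin, 13.0 for GAPDH and 2.72 for ubiquitin. The ratios also differed between tissues. The actin ratio was 2.62 ± 0.739 (SD, n = 3) in leaf, 5.75 ± 4.38 (SD, n = 4) in stem and 4.91 ± 2.27 (SD, n = 4) in flower. The ubiquitin ratio was 1.37 ± 0.217 (SD, n = 3) in leaf, 1.78 ± 0.662 (SD, n = 4) in stem and 2.06 ± 0.107 (SD, n = 4) in flower, where the lowest flower array (1.97) lay above the highest leaf array (1.62). GapC, the glycolytic gene to which the labels scale the arrays, had a deposited signal of 12653 ± 1785 (SD, n = 3) in leaf, 8325 ± 740 (SD, n = 4) in stem and 8249 ± 1459 (SD, n = 4) in flower. After quantile normalisation its log2 fold change was -0.19 in flower and -0.39 in stem versus leaf (adjusted p = 0.477 and 0.121), and 0.20 in flower versus stem (adjusted p = 0.389). With trimmed mean scaling the 3 differences were -0.62, -0.60 and -0.03, and with median centring -0.84, -0.56 and -0.28, so the last one turned negative.

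**Figure D1:**
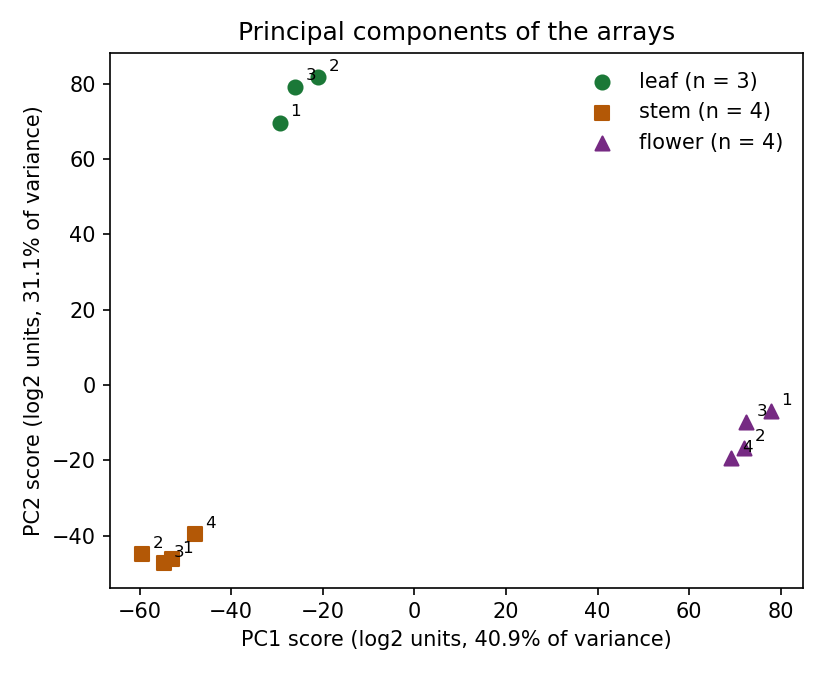
Scores of the 11 arrays on the first and second principal components of the normalised log2 values (log2 units; 40.9% and 31.1% of the variance). Points are arrays, coloured by tissue and numbered by replicate, and each tissue forms its own group.

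The contrast of flower with leaf asks which transcripts mark the reproductive organ. ATA27, an anther β-glucosidase, had a normalised intensity of 5677 ± 422 (SD, n = 4) in flower and 24.2 ± 12.6 (SD, n = 3) in leaf, a 103-fold difference (log2 6.69 ± 0.32 SE). THI2.1, an antimicrobial thionin, was 72.1-fold higher, and PLIM2a, a pollen LIM-domain protein that binds actin, 32.7-fold. PDF1.2, a plant defensin, was lower in flower, with a log2 fold change of -4.86 ± 0.30 (SE), as was THI2.2, another thionin, at -4.26 ± 0.25 (SE). The adjusted p was 6.1e-09 for ATA27, 3.9e-10 for THI2.1, 2.8e-09 for PLIM2a, 5.6e-08 for PDF1.2 and 2.9e-08 for THI2.2. Where the lower tissue was near or under the signal minimum, the size of the fold rested on the pseudocount: ATA27 was at 7.98 with a pseudocount of 1 and 5.54 with 100, PLIM2a at 6.35 and 3.87, PDF1.2 at -6.34 and -3.68, and THI2.2 at -5.28 and -3.25. The fold moved by over 1.5 times for 21 of the 40 genes named in this contrast.

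Among the other genes with the largest differences, GILT rose by 6.72, CYP71B31, a cytochrome P450, by 5.08 and RXF26 by 4.66 on the log2 scale. The log2 fold change was -4.75 for PDF1.2b, -4.30 for MSRB6, a methionine sulfoxide reductase, -4.00 for BCAT4, an aminotransferase of methionine-derived glucosinolate synthesis, and -3.21 for PYK10, a β-glucosidase of endoplasmic reticulum bodies. The highest adjusted p of these was 2.9e-04, for PYK10, and the arrays of the 2 tissues did not overlap for any of them.

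All 3 Calvin cycle genes tested, of the 14 in that list, fell in flower, 3 also adjusted over the list alone: RCA, rubisco activase, at -1.37 ± 0.21 (SE), PRK, phosphoribulokinase, at -1.3 ± 0.15 and SBPASE, sedoheptulose bisphosphatase, at -1.18 ± 0.19 log2 units. The list passed with the preset correlation (adjusted p = 0.0096; adjusted p = 0.193 with an estimated correlation). The 3 photorespiration genes tested, of 13, fell as well, 3 also adjusted over the list alone, with HPR, hydroxypyruvate reductase, at -1.70 ± 0.18 (SE), AT1G80380, glycerate kinase, at -1.50 ± 0.20 and AT1G11860, a glycine decarboxylase subunit, at -1.23 ± 0.16. That list had an adjusted p of 0.0067, and an adjusted p = 0.186 with an estimated correlation. LHCB4.1, a light-harvesting protein, fell by 1.15 log2 units (adjusted p = 7.4e-04).

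Tapetum genes rose together, 4 of 4 tested and 4 adjusted over the list alone (adjusted p = 0.0059; adjusted p = 0.134 with an estimated correlation). AT5G07230, the anther gene A9, rose by 4.03 ± 0.39 (SE), EMS1, the receptor kinase that specifies the tapetum, by 2.24 ± 0.34, SWEET8, a sugar transporter of pollen wall formation, by 2.16 and AMS, a transcription factor of the tapetum, by 1.76. Of 4 pollen genes 2 rose, ANX2, a receptor kinase of the pollen tube, by 1.68 and AGL104 by 1.44, with 2 adjusted over the list alone, and the list did not pass (adjusted p = 0.146). Cold and abscisic acid genes rose in 3 of 4 cases, 3 adjusted over the list alone: COR15A, a chloroplast protein of cold acclimation, by 2.80, COR47, a dehydrin, by 2.27 and COR15B by 1.94 (adjusted p = 0.0067; adjusted p = 0.193 with an estimated correlation). AUR1, a mitotic Aurora kinase, rose by 1.21 log2 units as the only called member of 3 mitotic genes, 1 adjusted over the list alone (adjusted p = 0.110 for the list). Flavonoid genes gave 1 lower of 4, and 2 lower adjusted over the list alone (adjusted p = 0.215). Heat shock genes gave 0 calls of 3, and 0 adjusted over the list alone (adjusted p = 0.617).

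Several families added after the probe table was seen also passed. SWEET sugar transporters had 8 higher and 3 lower of 14, with SWEET10 up by 3.37 and SWEET9, the nectary exporter, by 3.04, against SWEET2 at -2.17 and SWEET11, a phloem exporter, at -1.98 (adjusted p = 0.0198; adjusted p = 0.152 with an estimated correlation). SWEET8 stands in this family and among the tapetum genes. Serine carboxypeptidase-like genes had 8 higher and 2 lower of 23, with scpl47 at 3.65 and scpl38 at 3.19, against scpl46 at -3.04 and SCPL27 at -1.22 (adjusted p = 0.0067; adjusted p = 0.134 with an estimated correlation). RALFL genes, which encode small secreted peptides, had 4 higher of 8, led by RALFL25 at 4.1 and RALFL26 at 3.48 (adjusted p = 0.0059; adjusted p = 0.186 with an estimated correlation). The GH letters joined endoglucanases (GH9) with auxin-conjugating enzymes (GH3), and 4 of 13 rose, GH9B13 by 2.65 and GH9A4 by 2.58 (adjusted p = 0.0108; adjusted p = 0.152 with an estimated correlation).

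Glutamate receptor-like genes fell in 3 of 6 cases, with GLR2.7 at -3.20 and GLR2.8 at -1.24 (adjusted p = 0.0130; adjusted p = 0.152 with an estimated correlation). UGT glycosyltransferases had 5 lower and 1 higher of 24, with UGT76C1 at -2.27 and UGT72E1 at -2.21 against UGT85A3 at 1.09 (adjusted p = 0.0096; adjusted p = 0.158 with an estimated correlation). Their median turned to 0.0038 with the arrays scaled to GapC, but the median of all probe sets was then 0.68 and the list still passed (adjusted p = 0.0032). Autophagy (ATG) genes had 2 higher of 8, ATG8E by 1.62 and ATG8B by 1.61 (adjusted p = 0.0407; adjusted p = 0.364 with an estimated correlation). The ATG list did not pass without leaf replicate 2 (adjusted p = 0.0868), leaf replicate 3 (0.0639) or flower replicate 1 (0.0572), with site as a covariate (0.0556) or with any other scaling (0.0698 to 0.0882). SWEET was lost with GapC scaling (adjusted p = 0.115) and trimmed mean scaling (0.0572), and ATG and UGT with a signal minimum of 200 (0.0691 and 0.0744).

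In total 1608 probe sets were higher and 1626 lower in flower than leaf, 18.5% of those tested. With the arrays scaled to GapC these counts were 5025 and 617 (89.1% higher against 49.7%), and the median of all probe sets shifted by 0.70 log2 units to 0.68. Trimmed mean scaling shifted that median by 0.16. Tissue, age, RNA preparation and 3'/5' ratios differed together in this contrast. AT1G80380 (-0.92), GLR2.8 (-0.59) and SCPL27 (-0.44) lost their calls with GapC scaling, GLR2.8 (-1.0) and SCPL27 (-0.99) with trimmed mean scaling, and GLR2.8 (-0.72), SCPL27 (-0.92) and UGT85A3 (0.78) with a pseudocount of 100. GLR2.8 also lost it without leaf replicate 1 (-1.07) or 3 (-1.21) or flower replicate 3 (-1.11) or 4 (-1.07), SCPL27 without flower replicate 3 (-0.96), and UGT85A3 without leaf replicate 3 (0.72) or flower replicate 1 (0.98).

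The contrast of stem with leaf asks which transcripts mark the elongating axis. IRX15, needed for xylan of the secondary wall, had an intensity of 1321 ± 477 (SD, n = 4) in stem and 14.2 ± 1.66 (SD, n = 3) in leaf, a 27.6-fold difference (log2 4.79 ± 0.30 SE). Its relative IRX15-L was 20.7-fold higher, the expansin-like genes EXLA2 36.5-fold and EXLA1 20.9-fold, and GUT2, a xylan synthase subunit, 5.05-fold. LTI30, a dehydrin, was 23.9-fold higher. The adjusted p was 1.0e-07 for IRX15, 8.4e-06 for IRX15-L, 4.0e-06 for EXLA2, 2.9e-06 for EXLA1, 7.8e-05 for GUT2 and 1.7e-07 for LTI30. The size of the fold rested on the pseudocount for IRX15 (log2 6.35 with a pseudocount of 1 and 3.56 with 100), EXLA2 (5.65 and 4.53) and IRX15-L (5.09 and 3.67), and it moved by over 1.5 times for 12 of the 29 genes named in this contrast.

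LUP5, named for lupeol synthase, rose by 4.00 log2 units. THI2.2 was lower in stem at -4.46, PDF1.2b at -4.34, PDF1.2 at -4.24 and PYK10 at -3.69. TBL26 was at -3.33 ± 0.63 (SE) and scpl46 at -3.33 ± 0.39. The glucosinolate genes BCAT4 and UGT74B1 were at -1.81 and -1.02, and WSD1, a wax ester synthase, rose by 1.26 log2 units. The highest adjusted p of these was 0.0077, for UGT74B1.

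XTH genes, which encode xyloglucan-modifying enzymes, were higher in 5 of 7 cases, XTH19 by 3.37 and XTH18 by 3.32 (adjusted p = 0.0027; adjusted p = 0.218 with an estimated correlation). β-Tubulin genes were higher in 3 of 5, TUB6 by 1.91 and TUB1 by 1.77 (adjusted p = 0.0027; adjusted p = 0.218 with an estimated correlation). TBL genes, whose proteins include wall polysaccharide acetyltransferases, had 6 higher and 1 lower of 19, with TBL38 at 2.89 and TBL36 at 2.57 against TBL26 (adjusted p = 0.0099; adjusted p = 0.218 with an estimated correlation). Tetraspanins rose in 5 of 11 cases, TET2 by 1.57 and TET8 by 1.52 (adjusted p = 0.0080; adjusted p = 0.218 with an estimated correlation). The expansin family EXPA had 0 called of 7 and a median of -0.45 (adjusted p = 0.439), and PRA genes 3 higher of 10 (adjusted p = 0.0831).

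Cold and abscisic acid genes rose in 3 of 4 cases, 3 adjusted over the list alone, LTI30 by 4.58, COR47 by 3.47 and COR15B by 2.09 (adjusted p = 0.0023; adjusted p = 0.218 with an estimated correlation). UGT genes fell in 10 of 24 cases, with UGT87A2 at -2.62 and UGT72E1 at -2.37 (adjusted p = 0.0049; adjusted p = 0.218 with an estimated correlation). CRR genes, needed for the chloroplast NADH dehydrogenase-like complex, fell in 3 of 5 cases, with CRR41 at -1.78 and CRR42 at -1.29 (adjusted p = 0.0148; adjusted p = 0.218 with an estimated correlation). Flavonoid genes were lower in 3 of 4, UF3GT at -1.77, UGT78D1 at -1.53 and DFR, dihydroflavonol reductase, at -1.02, with 4 lower adjusted over the list alone (adjusted p = 0.0573 for the list).

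Plastid-encoded genes of the photosystems, cytochrome complex and ATP synthase were higher in stem in 13 of 32 cases, with a median of 0.96 log2 units (adjusted p = 5.0e-05; adjusted p = 0.385 with an estimated correlation). The photosystem II genes psbK and psbI rose by 3.45 ± 0.79 (SE) and 2.63 ± 0.46. The mean log2 intensity of this group was 12.6 to 12.7 in stem replicates 1, 2 and 4 and 11.8 in stem replicate 3, the array with the highest 3'/5' ratios. In leaf it was 10.8, 11.1 and 11.9, so leaf replicate 3 lay above stem replicate 3. The nuclear Calvin cycle and photorespiration genes did not pass, with medians of -0.50 and -0.60, 0 called of 3 in each and 0 adjusted over either list alone (adjusted p = 0.265 and 0.155). Tapetum (adjusted p = 0.688), pollen (0.843), mitotic (0.650) and heat shock genes (0.471) had 0 calls each, and 0 adjusted over the list alone.

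In total 1635 probe sets were higher and 1639 lower in stem than leaf, and with GapC scaling 3680 and 632 (85.3% higher against 49.9%), with a shift of the median of all probe sets by 0.50. Age and RNA preparation again went with tissue, and the mean actin 3'/5' ratio was 2.62 in leaf and 5.75 in stem. TBL (adjusted p = 0.0525) and CRR42 (log2 -0.82) lost their calls with GapC scaling, and UGT with a signal minimum of 200 (adjusted p = 0.0696). The flavonoid list passed without leaf replicate 1 or flower replicate 4 (adjusted p = 0.0181 for each) and with GapC scaling (0.0066), a pseudocount of 100 (0.0496), no filter (0.0300) or only the 2 tissues compared (0.0261).

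**Figure D2:**
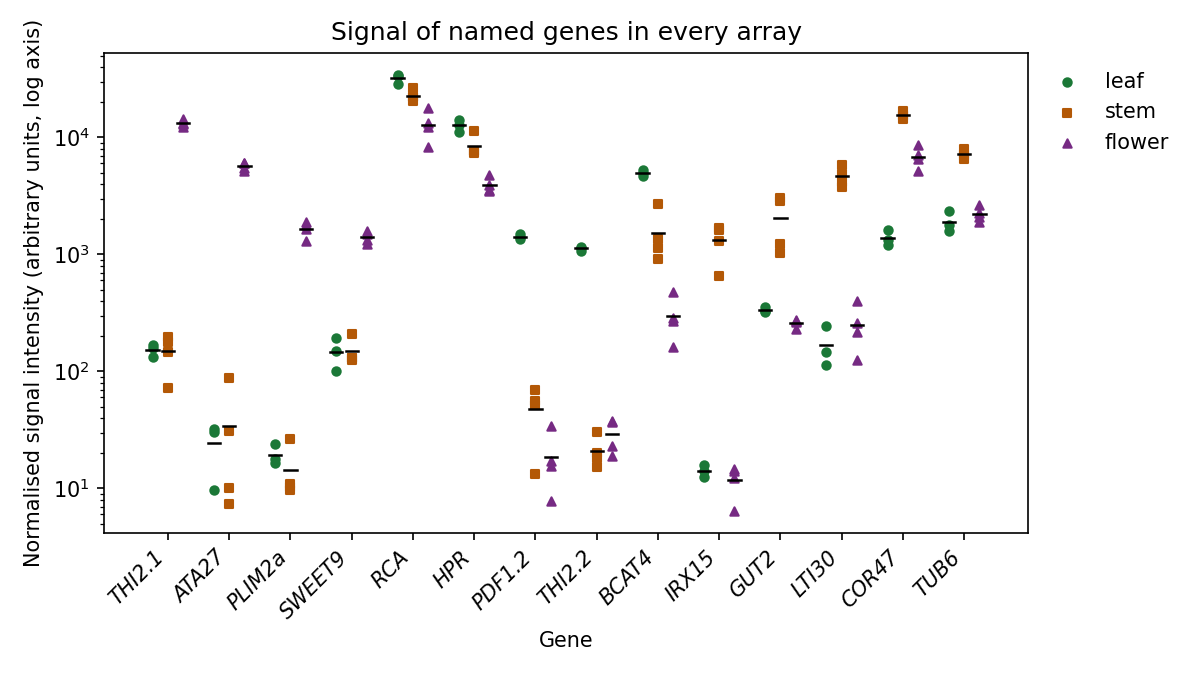
Normalised signal intensity (arbitrary units, log axis) of 14 genes in leaf, stem and flower. Points are arrays and black bars are means; ATA27, for example, averaged 5677 in flower and 24.2 in leaf, and IRX15 averaged 1321 in stem and 14.2 in leaf.

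The contrast of flower with stem compares organs harvested on the same day and prepared alike. Flower again carried more ATA27 (95.8-fold, log2 6.58 ± 0.30 SE, n = 4 each), THI2.1 (77.0-fold) and PLIM2a (36.6-fold), and OCT1, an organic cation transporter, was 22.9-fold higher. CYP71B31 and RXF26 rose by 4.68 and 4.49 log2 units. The log2 fold change in flower was -4.86 for IRX15, -3.84 for IRX15-L, -2.67 for GUT2, -3.78 for EXLA3, and -4.37 and -4.25 for the pectin methylesterase genes PMEPCRF and PME61. LTI30 fell by 4.12 log2 units. The highest adjusted p of these genes was 1.1e-05, for EXLA3. With a pseudocount of 1 and 100 ATA27 was at 7.97 and 5.46, OCT1 at 6.89 and 3.15, PLIM2a at 6.86 and 3.94, IRX15 at -6.65 and -3.59 and EXLA3 at -4.46 and -3.07, and the fold moved by over 1.5 times for 11 of the 37 genes named in this contrast.

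Tapetum genes rose in 4 of 4 cases, 4 adjusted over the list alone, AT5G07230 by 4.08 ± 0.36 (SE) and EMS1 by 3.14 ± 0.32 (adjusted p = 0.0029; adjusted p = 0.116 with an estimated correlation). Of 4 pollen genes ANX2 rose by 2.27, with 1 adjusted over the list alone (adjusted p = 0.254 for the list). Aurora kinase genes AUR2 and AUR1 rose by 1.22 and 1.11, 2 of 3 mitotic genes and 2 adjusted over the list alone (adjusted p = 0.0427; adjusted p = 0.317 with an estimated correlation). HPR fell by 1.1 as the only called gene of 3 for photorespiration, 1 adjusted over the list alone (adjusted p = 0.0369; adjusted p = 0.359 with an estimated correlation). The Calvin cycle list passed with a median of -0.87 and 0 called of 3, 0 adjusted over the list alone (adjusted p = 0.0432; adjusted p = 0.379 with an estimated correlation). Cold and abscisic acid genes went both ways, COR15A at 2.30 against COR47 at -1.20 and LTI30, 1 higher and 2 lower of 4 and the same counts adjusted over the list alone (adjusted p = 0.392). Flavonoid genes gave 1 higher, UGT78D1 at 1.63, also 1 adjusted over the list alone (adjusted p = 0.519), and heat shock genes 0, also 0 adjusted over the list alone (adjusted p = 0.891).

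SWEET transporters rose in 9 of 14 cases with 1 lower, SWEET4 at 4.34 and SWEET9 at 3.01 against SWEET16, a vacuolar transporter, at -1.69 (adjusted p = 0.0029; adjusted p = 0.116 with an estimated correlation). The LCR letters joined small cysteine-rich proteins with the cytochrome P450 gene LCR, and 3 of 5 rose, LCR66 by 3.83 and LCR72 by 3.12 (adjusted p = 0.0173; adjusted p = 0.317 with an estimated correlation). TBL genes had 6 lower and 1 higher of 19, with TBL38 at -2.17 and TBL34 at -1.81 against TBL26 at 3.34 (adjusted p = 0.0216; adjusted p = 0.231 with an estimated correlation). PRA genes, which encode prenylated Rab acceptors, were lower in 5 of 10, PRA1.B4 by a log2 fold change of -2.10 and PRA1.E by -1.37 (adjusted p = 0.0216; adjusted p = 0.317 with an estimated correlation). XTH genes fell in 4 of 7 cases, with XTH18 at -3.67 and XTH33 at -2.58 (adjusted p = 0.0369; adjusted p = 0.359 with an estimated correlation), and tubulin genes in 2 of 5, with TUB6 at -1.68 and TUB1 at -1.18 (adjusted p = 0.0427; adjusted p = 0.392 with an estimated correlation).

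Plastid-encoded ndh genes, which encode subunits of the NADH dehydrogenase-like complex, were lower in flower in 5 of 10 cases, ndhF by a log2 fold change of -2.91 and ndhG by -2.81 (adjusted p = 0.0102; adjusted p = 0.379 with an estimated correlation). The plastid photosystem, cytochrome and ATP synthase genes were lower in 6 of 32, petN by -1.71 and atpI by -1.64 (adjusted p = 0.0369; adjusted p = 0.727 with an estimated correlation). Stem replicate 3, with the highest 3'/5' ratios, had the lowest mean of both plastid groups among the stem arrays.

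In total 1727 probe sets were higher and 1419 lower in flower than stem (54.9% higher). GapC scaling gave 2211 and 1154 (65.7%), and median centring 1418 and 1872 (43.1%). The median of all probe sets shifted by 0.20 with GapC scaling, 0.17 with trimmed mean scaling and -0.08 with median centring. Without stem replicate 3 the Calvin cycle, photorespiration, mitotic, TUB and XTH lists did not pass (adjusted p = 0.0550 for each) and HPR was at -0.95. Other arrays also ended calls when each was left out in turn. Calvin cycle was lost without any leaf replicate, stem replicate 1, or flower replicate 1, 3 or 4 (adjusted p = 0.0504 to 0.0647), and mitotic without stem replicate 1 or 4 or flower replicate 1, 3 or 4 (0.0504 to 0.0585). TUB was lost without leaf replicate 3, stem replicate 1 or 4, or flower replicate 1 or 2 (0.0503 to 0.0697), XTH without flower replicate 1 (0.0575), and plastid photosystem without stem replicate 1, 2 or 4 or flower replicate 2 or 3 (0.0528 to 0.0891). The mitotic list was also lost with GapC scaling (adjusted p = 0.05005), and Calvin cycle, mitotic and TUB with a signal minimum of 200 (0.0506 for each). Calvin cycle was lost with only the 2 tissues compared (0.0628) and XTH with a pseudocount of 1 (0.0512). A replicate block ended the mitotic (0.0632) and TUB (0.0522) lists. AUR2 (0.94) and AUR1 (0.99) lost their calls with a pseudocount of 100.

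Single genes of the remaining fixed lists gave the following. HCT, a monolignol enzyme, was lower in flower than in leaf (-1.45) and stem (-1.98). AGL24, a flowering regulator, was lower in flower than stem (-1.68), and FD was at -0.06 (adjusted p = 0.939). EXPA4, an expansin, was higher in flower than stem (1.26), and EXPA8 was at 0.86 (adjusted p = 0.247). STZ, a stress-responsive zinc finger factor, was lower in flower than in leaf (-2.27) and stem (-1.60). WSD1 was higher in flower than leaf (2.19) and UGT74B1 lower (-1.78). GI, a clock gene, differed by at most 0.33 between tissues, with a lowest adjusted p of 0.153. Members of the floral organ identity, seed storage, meristem and vascular patterning, and jasmonate lists were not tested here.

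Called against both other tissues, 822 probe sets were enriched in leaf, 754 in stem and 828 in flower, and 553, 442 and 370 were depleted. With GapC scaling 258 were enriched in leaf and 1568 in flower, and 2067 were depleted in leaf, 260 in stem and 176 in flower. Median centring gave 556 depleted in flower.

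The contrast of greenhouse with growth chamber found 0 probe sets higher and 0 lower with limma. At an unadjusted p under 0.05 there were 1945, where 876 would arise by chance, and with the sites crossed by GapC factor there were 551. The lowest adjusted p was 0.0654, for GAMMA-VPE, a vacuolar processing enzyme, at a log2 fold change of -1.0 in the greenhouse. EXPA8 was at -1.62 and AT1G56220 at -1.28 (adjusted p = 0.134 for each), and these 3 genes were chosen after their values were seen. No list passed: heat shock had a median of -0.90 (adjusted p = 0.0638; 0 called, 1 lower adjusted over the list alone), and cold and abscisic acid -0.45 (adjusted p = 0.227; 0 adjusted over the list alone). The other fixed lists had 0 adjusted over the list alone and adjusted p-values of 0.227 (photorespiration) to 0.8.

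The heat shock list passed without leaf replicate 1 (adjusted p = 0.0267), leaf replicate 2 (0.0483) or stem replicate 3 (0.0307), and with GapC scaling (0.0082), a pseudocount of 100 (0.0495) or the protocol site for stem replicate 4 (0.0496). The cold and abscisic acid list passed without stem replicate 3 (0.0171). Without leaf replicate 1 the probe sets lower in the greenhouse numbered 14, without flower replicate 3 there was 1, and without flower replicate 1 there was 1 higher.

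The site effect itself was compared between tissues. Between stem and leaf it differed for 207 probe sets, 34 higher and 173 lower in stem, and psbH, a photosystem II gene, was at -5.39 (adjusted p = 4.9e-04) and petB, a cytochrome gene, at -2.45 (adjusted p = 0.0020). Between flower and stem it differed for 63, 61 higher and 2 lower in flower, with psbH at 2.77 (adjusted p = 0.0198) and petB at 1.99 (adjusted p = 0.0089). Between flower and leaf it differed for 24, 1 higher and 23 lower in flower, with Fes1A, a cochaperone of heat tolerance, at -4.21 (adjusted p = 0.0295). These genes were chosen after their values were seen. The greenhouse stem was 1 array, replicate 3, which had the highest 3'/5' ratios of the 11 arrays and the lowest plastid mean of the stems (11.8), and the growth chamber leaf was 1 array, replicate 1. These counts therefore cannot separate the site from those single arrays. With stem replicate 4 counted as greenhouse by its title code, the counts were 9, 0 and 11, and with stem replicate 3 also left out 11, 0 and 24. With stem replicate 4 counted as growth chamber by its protocol text they were 184, 101 and 11. With the sites crossed by GapC factor they were 8, 0 and 10, and with no filter on low values 135, 5 and 3. Leaving out each array gave 37 (without leaf replicate 2) to 223 (without flower replicate 4), 0 (without stem replicate 1) to 61 (without leaf replicate 1), and 1 (without flower replicate 1) to 71 (without flower replicate 3). Leaf had 1 site without leaf replicate 1, and stem had 1 site without stem replicate 3, so their site effects could not be compared there.

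**Figure D3:**
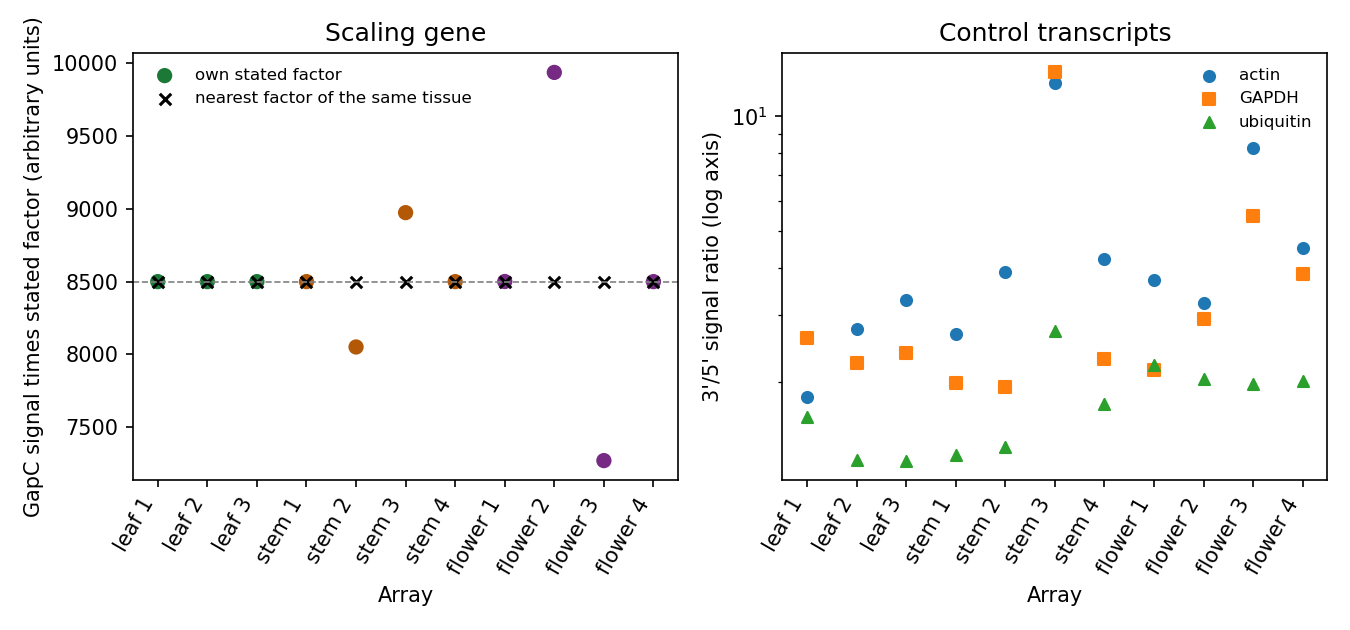
Left, deposited GapC signal times the stated factor (arbitrary units) per array, with each array's own factor (circles) and the nearest factor of its tissue (crosses); the dashed line is 8500, and own-factor products ranged from 7271 to 9936. Right, 3'/5' signal ratios of actin, GAPDH and ubiquitin (log axis) per array, highest in stem replicate 3 at 12.2, 13.0 and 2.72.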

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

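The splits of the tissue arrays and the tests of leaf and flower tissue in stem replicate 3 were planned before their results were seen. The tests of the site splits, of 3' bias, of greenhouse growth, of the GapC factors and of the plastid transcripts were chosen only after the result was seen. A sample was listed when its gap to the nearest other array of its tissue was large for the range of that tissue. Such gaps were looked for in 174 groups of values of the stem or flower arrays, and not among the leaf arrays. They were found in 17, where chance gives about 1 in 20, or 8.7. Of the 17, 8 lay in stem replicate 3.

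Every split of the arrays of a pair of tissues was fitted in turn. For flower and leaf, 1 of 35 splits gave as many calls as the real 3234, namely the real split, and the highest other gave 28. For stem and leaf it was 1 of 35, with 3274 calls and a highest other of 1154, from the split that put stem replicate 4 with the leaves. The next split put stem replicate 3 there and gave 1134. For flower and stem it was 1 of 35, with 3146 calls and a highest other of 4. For enriched probe sets it was 1 of 100 splits (the real one and 99 drawn at random), with 2404 and a highest other of 3. For these 4 results the real split stood alone, at a share under 0.05. Arrays of 1 tissue already resembled each other most, so mixed splits had a larger spread from the outset. The splits cannot exclude chance between plants or pools, which the labels do not give. For the sites the real count was 0, which 54 of 54 splits within tissues must reach, so that test decides nothing; the highest other split gave 7.

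Stem replicate 3 stood apart in 8 measures: a 3'/5' ratio of 12.24 for actin and 13.05 for GAPDH, 11.7% of the signal in the 50 strongest probe sets, a mean r of 0.908 with the other stems, a mean log2 value of 11.82 for plastid photosystem genes, and log2 values of 13.47 for HPR, 12.78 for psbK and 11.34 for TBL36.

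The test of leaf or flower tissue as the whole cause cannot decide. It asked how many probe sets at least 2-fold from the other stems lay outside the range of all 10 other arrays, since a mixture lies between its parts. In stem replicate 3 this was 65.3% of 1825 probe sets. Measured against its own tissue, every array exceeded the bound of 25% set for this test, and the highest other array had 54.0%. RNA degradation or 3' bias may account for part of the distance, since 3 of 3 control transcripts had their highest 3'/5' ratio in this array. Leaf or flower tissue in this array stays open. The median differences from the other stems were 0.0277 for 822 leaf-enriched and 0.0398 for 828 flower-enriched probe sets. Both lay within 3 standard errors of the median across probe sets, which are not independent. These medians cannot decide, since the enriched probe sets were called with stem replicate 3 among the stems. Greenhouse growth also stays open, as it is the only stem array with that site alone, and its difference correlated across probe sets at 0.185 with the flower and -0.0187 with the leaf site difference.

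The GapC factors stated for stem replicates 2 and 3 and for flower replicates 2 and 3 gave products between 7271 and 9936. An exchange within each pair is a candidate explanation: with the factors exchanged, all 4 products came within 0.0048 of 8500. Whether the factor texts or the value columns were exchanged cannot be told apart. Each pair joins a growth chamber and a greenhouse array, and crossing the sites gave 551 probe sets at an unadjusted p under 0.05 against 1945 as given, with 0 calls either way. No biological explanation was tested.

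Plastid photosystem genes were higher in stem than leaf by a median of 0.96 log2 units. Stem replicate 3 as the sole cause is argued against, since its mean of 11.82 for these genes was the lowest of the stem arrays; the median without it, 1.26, follows from that and adds no test of its own. More transcripts of nuclear Calvin cycle, photorespiration and light-harvesting genes in stem is argued against only for the 7 genes tested. These had a median of -0.50 and a highest value of -0.30. Of the 7, 3 were Calvin cycle and 3 photorespiration genes. Neither list passed with camera at the preset correlation (adjusted p = 0.265 and 0.155). Only 1 of 24 listed photosystem and light-harvesting genes was tested, so more nuclear photosystem transcripts in stem stays open. Column purification of stem and flower RNA may contribute and cannot be told apart from tissue and age. The flower versus leaf median of the plastid photosystem genes was 0.36. A difference between the organs or ages themselves stays open and untested.

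The difference of the site effect was tested by the interaction of tissue and site and gave 24 probe sets for flower and leaf, 63 for flower and stem and 207 for stem and leaf. Stem replicate 3 was the only greenhouse stem and leaf replicate 1 the only growth chamber leaf, so for all 3 counts the site and a single array cannot be told apart. In flower replicate 4 the mean r with the other flowers was 0.938. Its log2 values of 11.64 for GILT and 8.221 for XTH33 were far from the other flowers. AT1G80380 was at 9.421 in flower replicate 1 and TBL38 at 9.617 in flower replicate 2. Among the stems PLIM2a was at 5.868 in replicate 2, SWEET9 at 7.909 in replicate 1, and EMS1 at 7.354 and LUP5 at 9.216 in replicate 4. Outside stem replicate 3, such gaps were about as many as the 8.7 that chance gives in 174 groups.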

How the results depend on the processing

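Site assignments crossed by GapC factor, leaving out the 4 arrays concerned, and the title code without stem replicate 3 were chosen after seeing the data. Across the settings, named genes kept direction and side of the threshold in 2310 cases and lost the call in 19. Lists kept both in 1140 cases, lost the call in 80, gained it in 13 and turned direction in 1. Of the 80 losses, 31 came with an estimated correlation in camera. That setting ended every list call of the tissue contrasts (adjusted p = 0.116 to 0.727), so no list result held in all settings. Where a value below moved, the cause was not tested, except that no minimum fold adds calls by construction and leaving out arrays leaves fewer samples. For genes whose lower tissue was near or under the signal minimum of 100, background limits the size of the fold, which moved by over 1.5 times with a pseudocount of 1 or 100 for 21 of 40, 12 of 29 and 11 of 37 genes named in flower versus leaf, stem versus leaf and flower versus stem.

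Scaled to GapC, flower versus leaf gave 5025 higher and 617 lower, and stem versus leaf 3680 and 632; enriched were 258 in leaf and 1568 in flower, depleted 2067 in leaf, 260 in stem and 176 in flower; the site effect differed for 220 between flower and stem. The UGT list in flower versus leaf turned to a median of 0.0038, where the median of all probe sets was 0.68 and the list still passed (adjusted p = 0.0032). Trimmed mean scaling gave 321 for the site effect of stem minus leaf, and median centring 556 depleted in flower. A pseudocount of 1 gave site effect differences of 146 (flower minus stem) and 328 (stem minus leaf). A pseudocount of 100 gave 20 for flower minus stem, and 347, 242 and 217 depleted in leaf, stem and flower. No filter gave site effect differences of 3 (flower minus leaf), 5 (flower minus stem) and 135 (stem minus leaf). No minimum fold gave 2783 higher and 2830 lower in flower versus leaf, 2790 and 3249 in stem versus leaf, and 3178 and 3043 in flower versus stem. It gave 1713 enriched and 1147 depleted in leaf, 1466 and 1276 in stem, and 1455 and 1072 in flower.

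With a replicate block, the counts were 1601 higher and 1577 lower in flower versus leaf, 1635 and 1640 in stem versus leaf, and 1739 and 1426 in flower versus stem. The replicate block ended the mitotic (adjusted p = 0.0632) and TUB (0.0522) lists in flower versus stem. Residuals of arrays with the same number correlated at -0.16 to 0.15, over 0.1 in 3 of 10 pairs, and of pairs with different numbers 1 of 30 did, so the numbers were not taken to pair the arrays. All 3 were stem and flower pairs, whose 4 same-number correlations were 0.0893 to 0.150. Each of the 4 stem and 4 flower arrays correlated best with its own number in the other of these tissues (highest with another number 0.0891). Stem and flower arrays of the same number also shared the site of their title codes. All stem and flower pairs with different title-code sites correlated negatively, at -0.176 to -0.00086. The match by number may therefore follow the labelled site, and the labels give no pairing by number.

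With sites by title code, 1 probe set was lower in the greenhouse, and the site effect differences were 11, 0 and 9 (flower minus leaf, flower minus stem, stem minus leaf). By protocol text the first 2 were 11 and 101. Crossed by GapC factor they were 10, 0 and 8. Flower arrays alone, and the fit without those 4 arrays, gave 0 calls between sites. By title code without stem replicate 3, 1 probe set was lower in the greenhouse, and the differences were 0 for flower minus stem and 11 for stem minus leaf.

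Leaving out each array gave 0 to 1 probe sets higher in the greenhouse (1 without flower replicate 1) and 0 to 14 lower (14 without leaf replicate 1, 1 without flower replicate 3). The site effect differences ranged from 1 (without flower replicate 1) to 71 (without flower replicate 3) for flower minus leaf, 0 (without stem replicate 1) to 61 (without leaf replicate 1) for flower minus stem, and 37 (without leaf replicate 2) to 223 (without flower replicate 4) for stem minus leaf. Differences with leaf could not be fitted without leaf replicate 1, nor differences with stem without stem replicate 3, each the only array of its tissue and site. The remaining difference could be fitted in both cases, and was 23 for flower minus leaf without stem replicate 3. The tissue counts moved by less than 1.5 times, from 1428 (without leaf replicate 2) to 1715 (without leaf replicate 1) for stem versus leaf lower, for example. Leaving out the stem array of uncertain site is the same as leaving out stem replicate 4.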

Other observations

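The genes below were chosen after their values were seen, and no test of an explanation is given for them. Several of the largest differences lay in genes named here only by their locus. AT1G68875 had a normalised intensity of 9325 ± 1691 (SD, n = 4) in flower and 3.00 ± 1.24 (SD, n = 3) in leaf, a log2 fold change of 8.05 (adjusted p = 3.1e-10). With the leaf signal under the minimum of 100, that size rested on the pseudocount, at 11.22 with a pseudocount of 1 and 6.50 with 100. AT1G66850 was at 23928 ± 4319 (SD, n = 4) in flower, 7.51 log2 units above leaf (7.91 and 6.91 with those pseudocounts) and 7.58 above stem. AT3G07820 was higher in flower than leaf by 7.33 (9.83 and 5.87), AT2G47050 by 7.0 (8.41 and 5.80) and AT3G28830 by 6.68 (8.70 and 5.30). AT3G28830 lay below GILT and ATA27, but above both with a pseudocount of 1, where they were at 8.03 and 7.98. AT2G20870 reached 31026 ± 3067 (SD, n = 4) in flower, 7.24 log2 units above stem.

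In stem, AT1G22480 was at 7389 ± 1459 (SD, n = 4), 6.13 log2 units above leaf (6.65 with a pseudocount of 1 and 5.42 with 100), and its flower versus stem difference was -7.07 (-8.37 and -5.91). AT2G03200 was 5.61 above leaf (6.25 and 4.84), and AT3G23090 was at -5.66 in flower versus stem (-7.55 and -4.33). In leaf, AT1G23130 was at 5610 ± 75.4 (SD, n = 3) and at -6.98 in stem versus leaf (-8.73 and -5.66). AT1G66100 was at -5.87 in flower (-6.70 and -4.95) and -5.64 in stem (-6.28 and -4.83) versus leaf. AT2G33850 was near its leaf level in flower (2483 and 2250) and at -5.57 in stem versus leaf (-6.93 and -4.41).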
